A study of Mus musculus with 12 samples.

How the data were processed

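Allele reads were measured in F1 mice of 5 crosses between inbred strains: WSB/EiJ-MOLF/EiJ, FVB/NJ-PWD/PHJ, A/J-DBA/2J, CAST/EIJ-PWD/PHJ and A/J-C57BL/6J. An F1 animal inherits a set of chromosomes from each strain, so a SNP between the strains marks the parental copies of a transcript. Per the labels' protocols, liver and skeletal muscle came from 2 littermates per cross at 4 weeks of age, and about 0.6 g of tissue per cross and tissue (0.3 g from each littermate) went into total RNA, which was copied to cDNA with random hexamers. Genomic DNA (gDNA) came from about 50 mg of liver or muscle of a littermate. Each SNP was amplified separately from gDNA and from cDNA with the same primers, and cDNA reactions had matching controls without reverse transcriptase, per the labels' protocols. About 60 amplicons were mixed in equal molar amounts into each of 4 pools, which were pyrosequenced by the 454 method in separate segments of a plate, in 3 runs. Because of this mixing, the number of reads of an amplicon carries no information on expression, and only the ratio of the alleles within an amplicon was used.

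The deposited values are raw read counts of each of the 2 alleles of a SNP, per amplicon and run, with the template (gDNA, muscle mRNA or liver mRNA), the cross and the primers, per the file headers. The reads were not normalised. How reads were assigned to amplicons and alleles, which reads were filtered, and the genome build are not given in the sources used here. The allele listed first was the one with more reads in that file, and for 75 of the 89 SNPs its identity changed between files, so alleles were matched between files by base. No genome was used here, so positions of the SNPs, the genes that hold them and the strain that carries each allele are not reported. Of 228 combinations of SNP and template, 226 had reads in all 3 runs; rs30872764 had no run 3 counts in muscle and liver mRNA, and its sums there rest on 2 runs.

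Allele reads were summed over the 3 runs, since the runs sequence the same amplicons and are technical. For each SNP, the mRNA counts were set against the gDNA counts with Fisher's exact test (two-sided), and muscle mRNA against liver mRNA in the same way. The gDNA counts were tested against a share of 0.5 with an exact binomial test (two-sided). The p-values of each comparison were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and a minimum of 20 allele reads per template, which every SNP passed. Effects are ratios of allele ratios (fold) or their log2, with 0.5 added to each count, and have 95% intervals from the standard error of the log ratio. Shares are given as mean ± SD over runs, and intervals of single shares are 95% Wilson intervals. The study had 1 pool of animals and 1 amplification per cross, template and SNP. All p-values, intervals and standard errors therefore cover counting error only, and because PCR reads carry no molecular identifiers they are not independent molecules.

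Differences between the 3 runs of an amplicon were tested by a chi-square statistic with simulated p (9999 resamples). Means over SNPs were tested by permutation tests with 100000 resamples. The alternatives tried were a test stratified by run, a quasi-binomial model over runs, a test with extra variance between amplicons estimated from the gDNA ratios (SD 0.0759 on the log2 scale), minima of 10, 50 or no reads, a required 1.5-fold difference, mRNA against 1:1 without gDNA, and each run left out in turn. The tests per SNP or amplicon, these alternatives and the rule for naming SNPs were fixed before the data were examined; the tests of means over SNPs were not. By that rule, the text names for each imbalance comparison the 15 SNPs with the largest log2 ratio among those past the threshold with the same sign in all runs, and the 5 SNPs with the most reads among those not past it. For gDNA it names the 5 largest departures past the threshold. A SNP named for another reason is said to be chosen after its values were seen.

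The design also named 3 comparisons that were not run: the effect of an allele that destroys a microRNA site in the tissue of that microRNA, microRNA sites against control sites, and microRNA sites between tissues. They need to know which SNP lies in a miR-1, miR-133, miR-122 or control site and which allele keeps the site, and this assignment was not used here.

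The tests were tried on simulated data with the real depth of each SNP and known folds. For muscle mRNA against gDNA (75 SNPs), 32.0% of SNPs simulated with a 1.1-fold difference were called, 89.5% at 1.25-fold and 100% at 1.5-fold, and 1.23% of SNPs simulated without a difference. For liver mRNA against gDNA (64 SNPs) the shares were 27.5%, 94.0%, 100% and 1.25%, and for muscle against liver mRNA (50 SNPs) 34.0%, 92.0%, 98.5% and 1.92%. The simulated reads held counting error only, without spread between runs or amplification noise. These shares therefore do not give the rate of false calls in the real data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.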

Results

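Allele-specific read counts were obtained for 89 SNPs in F1 hybrid mice, all of them in gDNA, 75 in muscle mRNA and 64 in liver mRNA. There were 25 SNPs measured in muscle alone, 14 in liver alone and 50 in both tissues. By cross, 24 SNPs were from FVB/NJ-PWD/PHJ, 23 from CAST/EIJ-PWD/PHJ, 22 from WSB/EiJ-MOLF/EiJ, 17 from A/J-C57BL/6J and 3 from A/J-DBA/2J. PWD/PHJ, CAST/EIJ and MOLF/EiJ are inbred strains derived from wild mice, whereas A/J, C57BL/6J, DBA/2J and FVB/NJ are classical laboratory strains. Pool 1 held 60 gDNA amplicons, pool 2 held 29 gDNA and 26 liver amplicons, pool 3 held 53 muscle amplicons, and pool 4 held 38 liver and 22 muscle amplicons. The 3 runs gave 88107, 72840 and 71891 allele reads for pool 1, 74162, 82560 and 82330 for pool 2, 73429, 108526 and 94098 for pool 3, and 101347, 94128 and 41332 for pool 4. Summed over runs, a SNP had a median of 3870 reads in gDNA (835 to 11265), 4267 in muscle mRNA (488 to 18714) and 3904.5 in liver mRNA (947 to 10056).

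Genomic DNA, in which an F1 animal carries 1 copy of each autosomal allele, was the reference for the mRNA ratios. Most SNPs lay close to 1:1. The allele with more reads had a median share of 51.0%, and 80 of the 89 SNPs had both alleles between 45% and 55%. At 3 SNPs the skew was over 4-fold. The G allele of rs33901248 took 90.6% ± 0.896 of the gDNA reads (SD, n = 3 runs; 9.61-fold over C), the C allele of rs38561286 took 83.4% ± 1.68 (5.08-fold over T), and the T allele of rs30872764 took 80.6% ± 1.44 (4.14-fold over A). Smaller skews were found at rs32125166, with C at 65.3% ± 0.334 (1.88-fold over T), and at rs50990432, with C at 61.9% ± 2.96 (1.62-fold over T).

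By the exact binomial test, 22 of the 89 SNPs departed from 1:1 after adjustment, and these 5 were the ones with at least a 1.5-fold ratio. The other 17 called SNPs had ratios from 1.07-fold to 1.48-fold. The 95% Wilson intervals were 89.8% to 91.3% for rs33901248, 81.9% to 85.1% for rs38561286, 78.8% to 82.2% for rs30872764, 63.9% to 66.7% for rs32125166 and 60.0% to 63.6% for rs50990432. The rs33901248 amplicon was made with the primers TTGTCCCACAGAGGGAGACAG and CTCGATTGTCAGCTCTCCTGC, and that of rs32125166 with AAAGAGCTCCGAAGGAAGCTG and TTTCCAGCTCCTGTTGCTTGT.

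**Figure D1:**
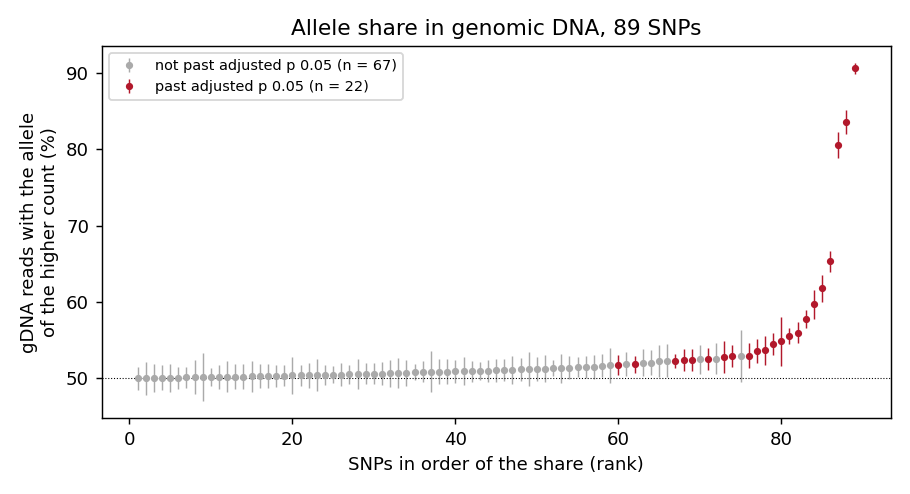
Share of gDNA reads with the allele of the higher count (%, y axis) for each of the 89 SNPs in order of that share (x axis, rank), summed over runs; bars are 95% Wilson intervals. Red marks the 22 SNPs past an adjusted p of 0.05, and the highest point is rs33901248 at 90.6%.

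Muscle mRNA was compared with gDNA to find alleles that differ in their transcript level in muscle, where the muscle microRNAs miR-1 and miR-133 are present. At 47 of 75 SNPs the alleles were imbalanced in muscle mRNA relative to gDNA. The strongest imbalance was at rs29317345 in the A/J-C57BL/6J cross, where the C allele made up 44.0% ± 1.56 of gDNA reads and 70.4% ± 1.07 of muscle mRNA reads (SD, n = 3 runs), a 2.99-fold shift of the ratio. The A allele of rs45902379 rose from 50.2% ± 2.54 in gDNA to 73.0% ± 2.00 in muscle mRNA (2.73-fold), the G allele of rs26888769 from 50.2% ± 1.27 to 70.9% ± 1.38 (2.42-fold), and the C allele of rs27858423 from 48.3% ± 2.62 to 68.1% ± 1.59 (2.25-fold). No other SNP reached 2-fold in this comparison.

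For these 4 SNPs the 95% intervals of the fold were 2.71 to 3.31, 2.49 to 2.99, 2.26 to 2.60 and 2.08 to 2.44, with adjusted p from Fisher's exact test of 6.37e-105, 2.33e-104, 1.41e-135 and 1.52e-87. At rs32125166 the T allele rose from 34.7% ± 0.334 in gDNA to 49.5% ± 0.965 in muscle mRNA, a 1.84-fold shift that left mRNA itself near 1:1. At rs33901248 the G allele, already favoured in gDNA, reached 93.7% ± 0.385 in muscle mRNA (1.54-fold). In the FVB/NJ-PWD/PHJ cross, imbalance of 1.47-fold to 1.80-fold was found at rs27412623 (T over C, 1.80-fold), rs27806858 (A over T, 1.58-fold), rs27583679 (G over C, 1.55-fold), rs27243453 (T over C, 1.501-fold) and rs32565756 (T over C, 1.47-fold). The A/J-C57BL/6J cross added rs29924703 (G over A, 1.65-fold) and rs29429994 (A over G, 1.52-fold), CAST/EIJ-PWD/PHJ added rs32579269 (G over A, 1.499-fold), and WSB/EiJ-MOLF/EiJ added rs36628412 (G over A, 1.58-fold). At rs29924703 gDNA was skewed towards A, and the G allele rose from 40.4% ± 1.71 in gDNA to only 52.8% ± 0.979 in muscle mRNA.

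Most imbalances were small. The median over the 47 called SNPs was 1.24-fold, and 13 reached 1.5-fold. Calls were made at 13 of 17 SNPs in WSB/EiJ-MOLF/EiJ, 13 of 20 in FVB/NJ-PWD/PHJ, 10 of 16 in A/J-C57BL/6J, 10 of 19 in CAST/EIJ-PWD/PHJ and 1 of 3 in A/J-DBA/2J. By the pools that held the mRNA and the gDNA amplicon, they were 22 of 34 for pools 3 and 1, 12 of 19 for pools 3 and 2, and 13 of 22 for pools 4 and 1. The direction was the same in all 3 runs for 46 of the 47 SNPs, the exception being rs31872413 (1.16-fold, named after its values were seen). Among SNPs not called, the 5 with the most reads were rs48781035 (1.03-fold, 95% interval 0.985 to 1.08), rs33350730 (1.04-fold, 0.973 to 1.11), rs37743849 (1.03-fold, 0.965 to 1.09), rs31663199 (1.002-fold, 0.938 to 1.07) and rs27772383 (1.001-fold, 0.930 to 1.08). The largest shift among the 28 SNPs not called was 1.13-fold. The number of calls fell to 25 with a quasi-binomial model over runs, under which rs36628412 was not called (adjusted p = 0.0577), and to 24 with extra variance between amplicons.

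Liver mRNA was compared with gDNA in the same way, liver being the tissue of miR-122. At 42 of 64 SNPs the alleles were imbalanced in liver mRNA. The largest shift was at rs36628412 in the WSB/EiJ-MOLF/EiJ cross, where the A allele rose from 49.9% ± 3.58 in gDNA to 71.6% ± 1.02 in liver mRNA (SD, n = 3 runs; 2.59-fold). At rs38561286, skewed towards C in gDNA, the C allele rose further from 83.4% ± 1.68 to 91.6% ± 1.22 (2.16-fold), and at rs51877709 the G allele rose from 50.4% ± 1.11 to 67.1% ± 2.35 (1.94-fold). The A allele of rs27073510 rose from 57.7% ± 1.35 to 69.6% ± 0.197 (1.67-fold).

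The 95% intervals of these folds were 2.27 to 2.96, 1.77 to 2.64, 1.71 to 2.19 and 1.57 to 1.79, with adjusted p from Fisher's exact test of 5.50e-44, 7.61e-14, 1.77e-24 and 3.27e-50. The rs36628412 amplicon was made with the primers AGCCACTGTAAGCAATGTGCC and AAGATGGTCCCCTTCAGCTTG. The WSB/EiJ-MOLF/EiJ cross held 6 more of the leading SNPs, namely rs27858423 (C over T, 1.66-fold), rs36610938 (G over C, 1.61-fold), rs13460373 (G over T, 1.53-fold), rs39724342 (T over A, 1.45-fold), rs32130254 (A over G, 1.45-fold) and rs48781035 (A over G, 1.39-fold). The others were rs33431534 (C over T, 1.59-fold) and rs29317345 (C over T, 1.49-fold) in A/J-C57BL/6J, rs27243453 (T over C, 1.52-fold) in FVB/NJ-PWD/PHJ, and rs27829110 (C over T, 1.45-fold) and rs13460433 (A over C, 1.44-fold) in CAST/EIJ-PWD/PHJ.

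The median over the 42 called SNPs was 1.30-fold, and 9 reached 1.5-fold. Calls were made at 15 of 17 SNPs in WSB/EiJ-MOLF/EiJ, 11 of 16 in CAST/EIJ-PWD/PHJ, 8 of 14 in FVB/NJ-PWD/PHJ, 7 of 16 in A/J-C57BL/6J and at the single SNP of A/J-DBA/2J. By pools of the mRNA and the gDNA amplicon, they were 17 of 26 for pools 2 and 1, 18 of 26 for pools 4 and 1, and 7 of 12 for pools 4 and 2. The direction was the same in all 3 runs for 39 of the 42 SNPs and not for rs52257281, rs48362062 and rs31785960, the last of which was named after its values were seen. The 5 SNPs with the most reads among those not called were rs33350730 (1.002-fold, 95% interval 0.939 to 1.07), rs37743849 (1.03-fold, 0.963 to 1.09), rs51083815 (1.02-fold, 0.947 to 1.11), rs48677813 (1.05-fold, 0.965 to 1.13) and rs27032232 (1.04-fold, 0.954 to 1.13). With extra variance between amplicons 26 SNPs were called. At the 50 SNPs measured in both tissues, liver calls fell from 33 to 22 with the quasi-binomial model over runs and to 21 with extra variance.

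Muscle and liver mRNA of the same SNP were then compared directly, which sets a transcript in the tissue of a microRNA against the same transcript in the other tissue. The allele ratio differed between the tissues at 31 of 50 SNPs. At rs36628412 the G allele made up 61.0% ± 3.85 of muscle reads and 28.4% ± 1.02 of liver reads (SD, n = 3 runs), a 4.10-fold difference between ratios on opposite sides of gDNA. At rs29317345 the C allele stood at 70.4% ± 1.07 in muscle and 54.0% ± 1.37 in liver (2.00-fold), at rs32579269 the G allele at 58.5% ± 1.38 and 42.3% ± 0.860 (1.91-fold), and at rs26888769 the G allele at 70.9% ± 1.38 and 56.9% ± 2.22 (1.89-fold).

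The 95% intervals of these folds were 3.64 to 4.63, 1.82 to 2.21, 1.74 to 2.09 and 1.76 to 2.03, with adjusted p from Fisher's exact test of 5.48e-122, 4.29e-45, 1.52e-43 and 6.16e-70. All 31 called SNPs differed in the same direction in all 3 runs. Next in size were rs13460373 (T over G higher in muscle, 1.83-fold), rs50990432 (C over T, 1.78-fold), rs29429994 (A over G, 1.63-fold) and rs52257281 (A over G, 1.60-fold). Differences of 1.35-fold to 1.48-fold were found at rs38362016 (C over T, 1.48-fold), rs30896490 (A over G, 1.46-fold), rs29924703 (G over A, 1.43-fold), rs46192522 (C over T, 1.42-fold), rs33431534 (T over C, 1.36-fold), rs30114270 (C over T, 1.36-fold) and rs48362062 (A over G, 1.35-fold).

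**Figure D2:**
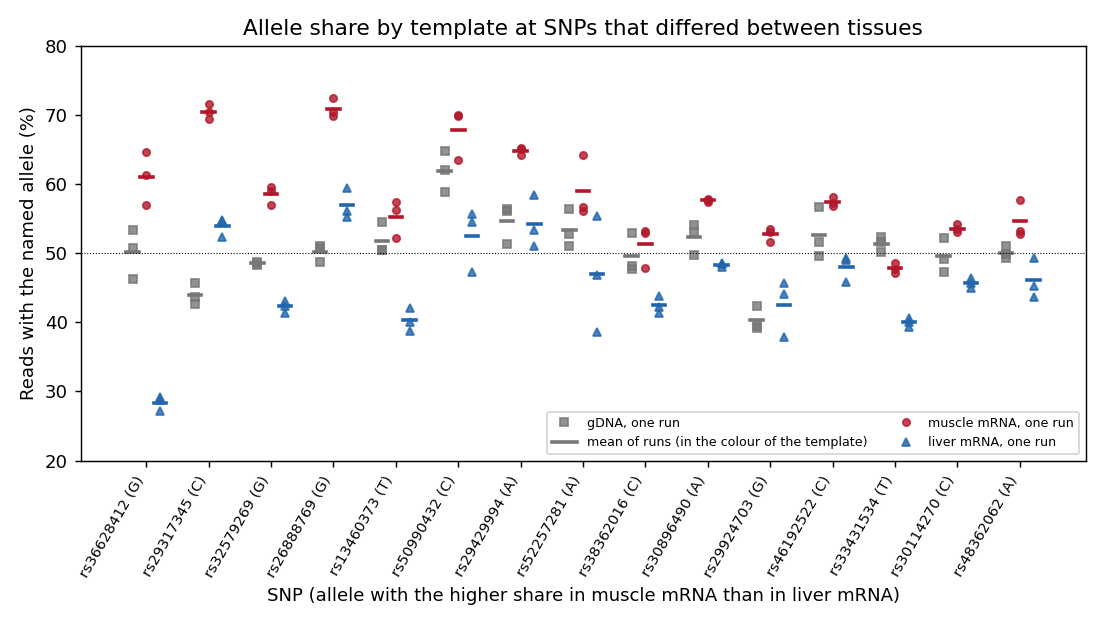
Share of reads (%, y axis) with the allele that is higher in muscle than in liver mRNA, at the 15 leading SNPs of the tissue comparison (x axis), in gDNA (grey squares), muscle mRNA (red circles) and liver mRNA (blue triangles); each symbol is a sequencing run and lines are means of runs. At rs36628412 the G allele stands at 61.0% in muscle and 28.4% in liver.

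Calls between tissues were made at 10 of 12 SNPs in WSB/EiJ-MOLF/EiJ, 10 of 15 in A/J-C57BL/6J, 5 of 10 in FVB/NJ-PWD/PHJ, 5 of 12 in CAST/EIJ-PWD/PHJ and at the single SNP of A/J-DBA/2J. By pools of the muscle and the liver amplicon, they were 18 of 28 for pools 3 and 4 and 13 of 22 for pools 4 and 2. In each imbalance comparison the templates of a SNP lay in different pools, so template and pool cannot be separated. The SNPs with the most reads among those not called were rs37743849 (1.001-fold, 95% interval 0.940 to 1.07), rs32154199 (1.02-fold, 0.951 to 1.09), rs33350730 (1.04-fold, 0.970 to 1.11), rs36333425 (1.05-fold, 0.973 to 1.14) and rs51083815 (1.07-fold, 0.989 to 1.16). With a quasi-binomial model over runs, rs50990432, rs52257281 and rs48362062 were not called (adjusted p = 0.0666, 0.0788 and 0.0684), and without run 2 rs51083815 was called (adjusted p = 0.0173). A required 1.5-fold difference left 8 SNPs.

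Of the 50 SNPs in both tissues, 27 were called against gDNA in muscle and in liver. At 17 of them the same allele was favoured relative to gDNA, among them rs29317345, rs27858423, rs26888769, rs27806858 and rs27243453. At rs27243453 the tissues did not differ by a detectable amount (T over C, 1.501-fold in muscle and 1.52-fold in liver, adjusted p = 0.835 by Fisher's exact test of the difference). At the other 10 SNPs the tissues favoured opposite alleles relative to gDNA, namely rs36628412, rs32579269, rs13460373, rs50990432, rs52257281, rs38362016, rs30896490, rs46192522, rs30114270 and rs48362062. At rs50990432 the C allele held most of the summed reads in both tissues (67.5% in muscle, 53.9% in liver). Its liver shift towards T rests on the gDNA skew (61.8% C). The split of 17 against 10 was not distinguishable from an even split (exact binomial test, two-sided, p = 0.248). The number of calls in the same direction fell from 17 to 9 with extra variance between amplicons and to 9 with the quasi-binomial model. The number of opposite calls was 6 without run 1, 8 without run 2 and 5 without run 3, and was 2 with extra variance between amplicons (rs36628412 and rs32579269) and 2 with the quasi-binomial model (rs30896490 and rs32579269).

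Since muscle and liver were set against the same gDNA reads, chance errors in gDNA are common to both. Over the 50 SNPs, the covariance of the log2 shifts in muscle and liver was 0.0551, against 0.00282 in 1000 simulations of unchanged mRNA that shared the gDNA reads, a difference of 0.0522. The correlation was 0.306 observed and 0.458 simulated. The simulated correlation comes from the shared gDNA alone, without any shift of mRNA, so these correlations are not directly comparable. The simulated reads held counting error only, so other errors in the shared gDNA may add to the observed covariance. Independent lists of the same lengths would hold 10.46 SNPs called in both tissues in the same direction, against the 17 observed; with extra variance the numbers were 2.88 and 9, and with the quasi-binomial model 3.32 and 9. In 100 simulations without any effect the mean was 0; since hardly any SNP is called without an effect, this does not measure likeness between the tissues. SNPs are not independent replicates, and part of the excess may come from the shared gDNA.

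**Figure D3:**
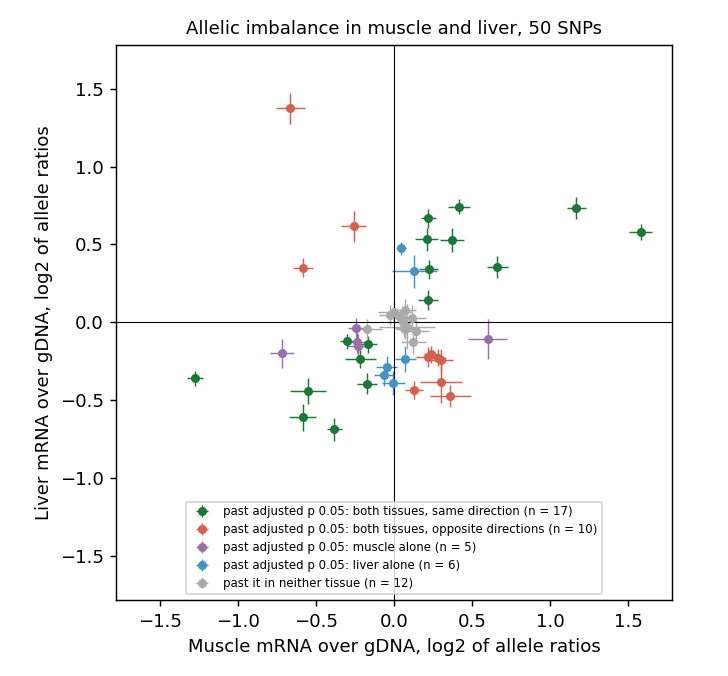
Shift of the allele ratio in muscle mRNA (x axis) and liver mRNA (y axis) relative to gDNA, as log2 of the ratio of allele ratios for the base that comes first in the alphabet, for 50 SNPs; bars are standard errors from counting, and colours give the tissues in which a SNP passed an adjusted p of 0.05. The 17 SNPs in green were called in the same direction in both tissues and the 10 in orange in opposite directions, with rs36628412 at the top left.

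The SD of an allele share over the 3 runs had a median of 1.46 percentage points over 226 amplicons. Allele counts differed between runs at 8 amplicons after adjustment (32 at an unadjusted p under 0.05), namely 3 of 60 in pool 1, 1 of 54 in pool 2, 2 of 53 in pool 3 and 2 of 59 in pool 4. They were the gDNA amplicons of rs36610938, rs46192522 and rs36830095, the muscle amplicons of rs13474726 and rs30175876, and the liver amplicons of rs48362062, rs49610656 and rs50990432; those outside the naming rule were named after their values were seen. The largest SD was 8.43 percentage points at rs52257281 in liver, which was not called (adjusted p = 0.181 by the chi-square test with simulated p), and the next was 8.02 at rs13474726 in muscle, which was. The mean chi-square per degree of freedom between runs, 1 where counting is the only error, was 1.88, 1.40, 1.86 and 1.74 in pools 1 to 4.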

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

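Tests of the gDNA skew, of the opposite calls under extra variance and the quasi-binomial model, of single amplification and of other splits of the reads were chosen after the results were seen. The tissue difference under extra variance and the test by pools were chosen before their own results were seen, but after the SNPs of opposite direction were known.

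The difference between muscle and liver was called (Fisher's exact test, two-sided, adjusted) at 31 of all 50 SNPs measured in both tissues. The 21 of these that the rule names are listed here, out of 30 named; the naming rule largely fixes that count, since it took 15 SNPs for passing this test and 5 for not passing it. On the log2 scale, muscle over liver, the allele ratios differed by 2.04 at rs36628412 (G over A), 1.002 at rs29317345 (C over T), 0.93 at rs32579269 (G over A), 0.92 at rs26888769 (G over A), 0.87 at rs13460373 (T over G), 0.83 at rs50990432 (C over T), 0.71 at rs29429994 (A over G) and 0.68 at rs52257281 (A over G). The difference was 0.56 at rs38362016 (C over T), 0.54 at rs30896490 (A over G), 0.52 at rs29924703 (G over A), 0.51 at rs46192522 (C over T), 0.45 at rs33431534 (T over C), 0.44 at rs30114270 (C over T), 0.44 at rs48362062 (A over G), 0.44 at rs27858423 (C over T) and 0.43 at rs48781035 (G over A). Smaller values were found at rs32130254 (G over A, 0.32), rs27073510 (G over A, 0.32), rs27806858 (A over T, 0.31) and rs36610938 (C over G, 0.30).

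The pattern to follow up first is the 10 SNPs whose ratios in muscle and liver shifted towards opposite alleles relative to gDNA, led by rs36628412. At rs50990432 the uncorrected reads favoured C in both tissues, and the liver shift towards T rests on the gDNA skew. With extra variance of the size seen between gDNA amplicons, all 10 still differed between the tissues after adjustment over the 50 SNPs. These SNPs were picked for shifts on opposite sides of gDNA and all 10 were already called between tissues, so the choice favours that outcome. It therefore does not decide on such noise as the source of the tissue difference. With the quasi-binomial model over runs 3 of them (rs50990432, rs52257281 and rs48362062) no longer passed, at the same log2 differences (0.83, 0.68 and 0.44). That model takes in spread between runs of the same amplicons, which is not amplification noise. Only 2, rs36628412 and rs32579269, still passed against gDNA on both sides with extra variance, and rs36628412 lost its muscle call with the quasi-binomial model (adjusted p = 0.0577). For the other 8 the crossing of the gDNA level itself stays open. The extra variance was taken between SNPs with 1 gDNA amplification each, so it also holds any fixed allele bias of the primers. Noise between repeat amplifications was not measured. The SNPs lay at 8 of 28 in pools 3 and 4 and at 2 of 22 in pools 4 and 2 (Fisher's exact test, two-sided, p = 0.154), too few to decide on a pool effect. Each SNP had 1 amplicon per tissue, so few cDNA molecules in a single amplification stay possible, as does a tissue difference in regulation of the alleles, which was not tested.

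A second pattern is the gDNA skew of over 4-fold at rs33901248, rs38561286 and rs30872764. An extra genomic copy that is not transcribed would leave mRNA near 1:1, but the smallest uncorrected mRNA log2 ratio was 0.960 of the gDNA log2 ratio, at rs30872764 in muscle. A candidate explanation is an allele bias of the primers common to gDNA and mRNA, which alone predicts a value near 1; this held at rs30872764 (0.960 in muscle, 1.01 in liver), but rs38561286 in liver gave 1.47 and rs33901248 in muscle 1.19, so a real imbalance on top, a bias that differs by template or a transcribed extra copy stays open. At rs32125166, where gDNA stood at 65.3% for C, muscle mRNA held 50.6% (95% Wilson interval 49.3% to 51.9%), as an untranscribed extra copy would give. A real imbalance towards T that offsets a primer bias would give the same value, and no biological explanation was tested.

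Each imbalance count was also set against other splits of the 6 sets of reads, 3 against 3. In each comparison the real split was the 1 of 10 with the most calls, but 10 splits are too few for a share under 0.05. The runs sequence the same amplicons, and a split that mixes templates averages their ratios. The real split would therefore lead whatever made the amplicons differ, and the counts do not tell a cause. The real and the highest other counts were 47 and 25 for muscle mRNA against gDNA, 42 and 24 for liver mRNA against gDNA, and 31 and 18 for muscle against liver mRNA.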

How the results depend on the processing

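Alternatives without SNPs skewed in gDNA and with a shared spread between runs were added after seeing the data, as were all alternatives for calls in both tissues; the first pair did not move a count by over 1.5 times. Muscle calls against gDNA were 25 with the quasi-binomial model and 24 with extra variance (47 reported). Liver calls were 26 with extra variance (42 reported). With the quasi-binomial model they were 22 at the 50 SNPs in both tissues (33 in the reported test). A required 1.5-fold difference left 13 calls in muscle, 9 in liver, 8 between tissues and 5 in gDNA, by construction. Calls in both tissues were 9 in the same direction (17 reported) and 2 in opposite directions (10 reported), both with extra variance and with the quasi-binomial model, and the latter ranged from 5 to 8 with a run left out, where fewer reads are tested. Minima of 10, 50 or no reads removed no SNP or amplicon and test nothing. Run numbers do not pair the pools: same-numbered deviations correlated from -0.43 to 0.36, and with run as a replicate block 45, 42 and 31 SNPs were called.

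Of 610 values for named SNPs under alternatives, 584 kept direction and side of the threshold and 19 changed sign. The 584 include 65 values at each of the minima of 10, 50 and no reads, which could not change. Many of the rest belong to SNPs named for large shifts, so these counts do not measure how stable the calls are. In all, 5 values lost the call, 1 of them with a change of sign, and 5 gained it, 2 of them with a change of sign (rs27772383 in muscle and rs33350730 in liver, without gDNA correction). All but 1 of the sign changes were at SNPs not called in the reported test. With the replicate block the log2 was -0.0021 at rs31663199 (muscle), -0.0039 at rs33350730 (liver) and -0.0055 at rs37743849 (between tissues). Without gDNA correction it was 0.035 at rs32125166 (called when reported, through its gDNA skew), -0.048 at rs33350730, -0.053 at rs31663199 and 0.14 at rs27772383 in muscle, and -0.075 at rs48677813 and -0.10 at rs33350730 in liver. With a run left out, muscle values ranged from -0.0070 to 0.10 at rs37743849, -0.017 to 0.024 at rs31663199 and -0.027 to 0.022 at rs27772383. Liver values ranged from -0.020 to 0.087 at rs37743849, -0.092 to 0.030 at rs51083815, -0.031 to 0.019 at rs33350730 and -0.014 to 0.15 at rs48677813. Between tissues they ranged from -0.062 to 0.043 at rs32154199, -0.0030 to 0.094 at rs33350730 and -0.016 to 0.013 at rs37743849. The cause of these changes was not tested. The alternatives planned for the 3 microRNA site comparisons were not run.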

Other observations

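The test over crosses was chosen after the values were seen. The tests on gDNA in the WSB/EiJ-MOLF/EiJ cross, on that cross without rs36628412 and on G or C alleles were chosen after the data had been examined, but before their own results were seen. Once these were seen the bounds were made stricter, by a margin of 2 SE for the first pair and by asking for both sets of SNPs for the last, and the test of the cross without rs36628412 in liver was added.

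Imbalance was larger in the WSB/EiJ-MOLF/EiJ cross. In liver mRNA against gDNA the mean absolute log2 was 0.49 over its 17 SNPs and 0.25 over the other crosses (permutation test, two-sided, p = 0.00223, adjusted p = 0.0268 over 12 tests). Between tissues it was 0.59 over 12 SNPs and 0.27 in the others (adjusted permutation p = 0.0417). The test was chosen after the values were seen and treats SNPs as exchangeable, so it does not settle a chance draw of SNPs. In muscle mRNA against gDNA the difference was not distinguishable from chance (0.37 and 0.30, adjusted permutation p = 0.688), and larger gDNA departures in that cross are argued against by their mean of 0.0968 ± 0.0325 (SE), below the 0.24 to be explained (difference from the other crosses -0.12, or -0.0090 ± 0.0373 without the 3 SNPs skewed over 4-fold). Without rs36628412 the difference from the other crosses went from 0.24 ± 0.09 (SE) to 0.18 ± 0.07 in liver (permutation p = 0.00936, adjusted p = 0.0562) and from 0.32 ± 0.16 to 0.18 ± 0.10 between tissues (permutation p = 0.0443, adjusted p = 0.266), and with these smaller differences neither passed the adjustment over 12 tests. In each adjustment the other comparison still held rs36628412, so the adjusted p in liver is lower than with that SNP out of both. The cross still stood above every other, but by less than 2 SE. It was at 0.43 against 0.27 for the next in liver (difference 0.16 ± 0.10) and 0.46 against 0.36 between tissues (0.10 ± 0.12). The 0.18 left in liver was over 2 SE but did not pass the adjustment, and its test was added after the values were seen. That SNP as the whole source therefore stays open in liver and between tissues. The cross may hold more divergent regulation, but it was represented by a single pair of littermates and its own set of SNPs, so animals, SNP choice and strains cannot be separated.

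The small gDNA departures were tested for a lower yield of the G or C allele than of the A or T allele. Over the 76 SNPs of this kind under 1.5-fold, the mean log2 of G or C over A or T was -0.048 (sign-flip permutation test, two-sided, p = 0.000990), with 44 SNPs below 0 (exact binomial p = 0.207). Over all 79 such SNPs the mean was 0.0042 (sign-flip permutation p = 0.936), so the hypothesis was not settled.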
